A study of Homo sapiens with 3 samples.

How the data were processed

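Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in MDA-MB-231, an established cell line from a triple-negative breast cancer that carries the p53 missense mutant R280K. Per the labels' protocols, cells of passages 10 to 20 from 6 plates per immunoprecipitation were fixed in 1% formaldehyde for 20 min. The chromatin was sonicated for 30 min to fragments averaging 250 to 300 bp, and TruSeq libraries were sequenced on a HiSeq instrument as single reads of 50 bp (the read length is stated for the DO1 and input libraries). The series holds 3 libraries with 1 library per group: a ChIP with the mouse p53 antibody DO1, an input and a ChIP with non-specific mouse IgG. The library titled input carries IgG in its antibody field, so its nature is ambiguous in the labels, and it is called the input here by its title. Per the labels, the IgG library served only for local read quantification.

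The 1 processed file analysed here is the peak list of the DO1 library against the input. Per the submitters' processing notes, the processing used BWA 0.6.2, SAMtools and MACS (version not given in the sources used here), and the builds listed are hg19 and mm9. Coordinates are taken as hg19, because the list names 23 human chromosomes and only 10.7% of the peaks with a matched gene lay inside that gene's span (with 5 kb either side) in a gene table of GRCh38. The peaks were called on a single library, so no replicate was pooled or compared. Per the file headers, each peak has its position, width, summit, tag count, fold enrichment, a score made from the p-value, false discovery rate (FDR) and the closest gene with its distance to the transcription start site (TSS).

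The deposited tag count is a whole number of reads per peak and is not normalized. The deposited fold enrichment is a ratio of ChIP signal to the peak caller's background estimate. It does not follow the listed tag count alone, since peaks of 64 and 21 tags had the same fold of 50.65. The deposited significance is a score of 10 times the usual −log10 p-value, and the FDR is deposited in percent; in MACS such an FDR compares the ChIP with a swapped analysis of the control. Every peak in the list had a fold of at least 10 and a score of at least 50; no label or header states these thresholds. The annotation that named the genes is not given in the sources used here. In the 805 pairs of peaks checked, the first and second listed for each deposited gene name with several peaks (798 of these names were matched to a gene, as below), the deposited distances differed as the peak centres did, within 1 bp, so the distance is that of the peak centre to the TSS. A gene is named only within 5 kb of its TSS, and each peak names at most 1 gene, so genes that share a promoter can lose a peak to their neighbour.

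From these values, peaks were described by distance to the TSS, strength and chromosome, and genes by whether a peak lay within 5 kb of the TSS. Of 3697 gene names, 3365 were current symbols, 311 were matched through older symbols in the GRCh38 gene table and 21 had no unambiguous match. The table was used for names, gene type and chromosome only. The background was its 19974 protein-coding genes on the autosomes and X, of which 3661 (18.3%) had a peak. A total of 19 gene lists was compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists; odds ratios have exact 95% intervals. The lists were proteasome, canonical wild-type p53 targets, NRF2 targets, cell cycle genes with NF-Y promoters, mevalonate and sterol genes, nucleotide synthesis, chromatin methyltransferases and acetyltransferases, ubiquitin and p97 genes, heat shock and chaperonin genes, core spliceosome, cytosolic ribosomal proteins, complex I, basal and mesenchymal genes, luminal genes, immune and blood genes, the p53 family with the NRF2 axis and partner factors, matrix and adhesion genes, long neuronal genes and olfactory receptors. Lists, tests and the rule for named genes were fixed before the data were examined. The rule named the 10 TSS-near peaks and the 5 peaks overall with the highest fold, up to 10 proteasome genes by fold, and up to 4 genes by fold in each other list; where a gene had several peaks, the peak with the highest fold was used. Genes named as having no peak, and PSME2, were chosen after their values were seen. Some genes that the rule names are not reported here.

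Fold enrichment of TSS-near peaks and other peaks was compared by a two-sided permutation test of medians with 100000 resamples, with a bootstrap interval from 2000 draws. Peaks per chromosome were compared with the share of protein-coding genes by exact binomial tests, since chromosome lengths were not used here. Shares have 95% Wilson intervals, which cover counting error only. Genes and peaks are not replicates of the experiment, and with 1 DO1 library no test between samples was possible. Library totals were not given in the sources used here, so the depth is known only as tags per peak.

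The enrichment test was tested on simulated data with 19974 genes. In 100 simulations it called a planted odds ratio of 3 in the proteasome list 85 times, an odds ratio of 5 in the spliceosome list 97 times and an odds ratio of 3 in the ribosomal protein list 99 times. Among 1600 tests of unchanged lists it made 11 calls (0.688%). The simulated genes drew peaks independently and, outside the planted lists, at a single rate. These counts therefore do not cover clustered peaks or genes that differ in their chance of a peak. The alternatives were the 4734 peaks with the best p-value, the 4795 with the highest fold, the list without dense clusters (10 or more peaks within 500 kb), a 1 kb TSS window, a background without olfactory receptor genes, an FDR of at most 1% or 5%, merging within 1 kb, and splitting of readthrough gene names. Sequence motifs were not analysed, because no genome sequence was used here. Analyses were run in Python 3.11.15 with scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.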

Results

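Binding of the p53 mutant R280K to chromatin was profiled by ChIP-seq in MDA-MB-231 breast cancer cells with the antibody DO1, which recognises the N-terminal part of p53. The title of the series places the proteasome, the protease complex that degrades ubiquitin-tagged proteins, at the centre of a program shared by p53 missense mutants. The peak list of the single DO1 library, called against the input, held 9433 peaks on 23 chromosomes. The peaks covered 2232672 bp and held 141143 tags. The median peak was 194 bp wide (range 64 to 2105) and held 11 tags (range 7 to 838) at a fold enrichment of 14.3 (range 10 to 50.65). Many peaks were supported by few reads: 4451 peaks (47.2%) had 10 tags or fewer. By the peak caller's FDR, 5026 peaks (53.3%) were at 5% or less and 2845 (30.2%) at 1% or less, and the highest FDR in the list was 20.8%. There was no replicate of any library, and the input and IgG signals at these peaks were not analysed here, so the values below describe this one peak list.

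The first question was where the peaks lay relative to genes. DO1 peaks gathered at transcription start sites: 4688 peaks (49.7%, 95% Wilson interval 48.7 to 50.7) had their centre within 5 kb of a TSS and 3062 (32.5%, interval 31.5 to 33.4) within 0.5 kb. Among the TSS-near peaks the median distance was −25 bp (negative is upstream), and 65.3% lay within 0.5 kb against 3.2% between 4 and 5 kb. The number of peaks per 0.5 kb bin was 1692 just upstream and 1369 just downstream of the TSS, and 28 and 32 in the outermost bins. Peaks of higher significance were more often near a TSS: the share was 65.5% (interval 62.4 to 68.4) among the 944 peaks with the best p-values and 42.3% (interval 39.1 to 45.4) among the 944 with the weakest. In all, 3661 protein-coding genes had a peak, and 798 genes had 2 or more.

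**Figure D1:**
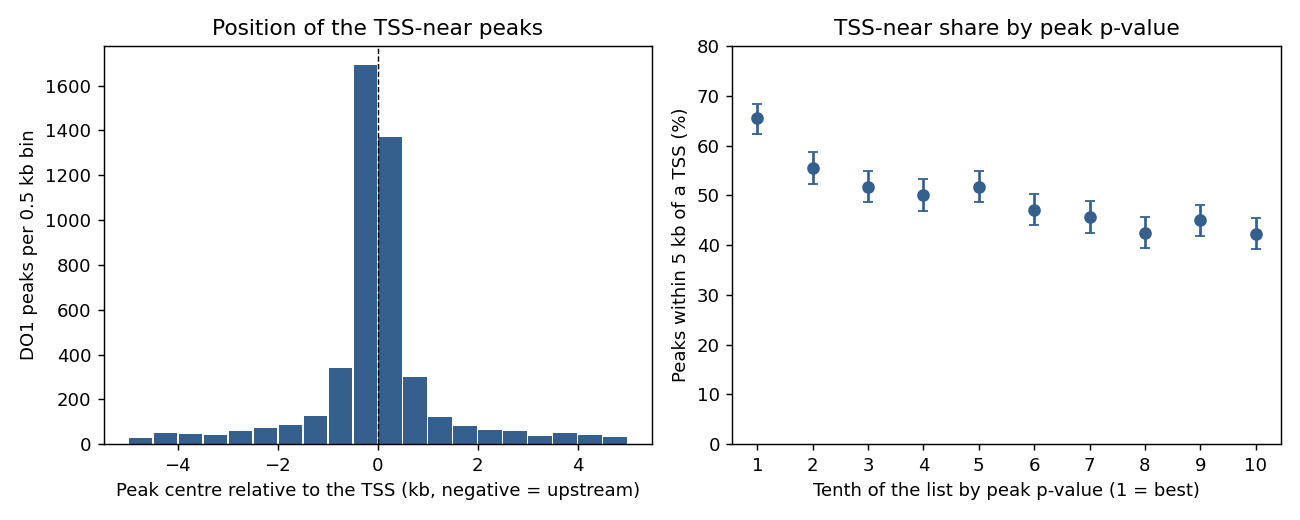
Left, number of DO1 peaks per 0.5 kb bin (y axis) by distance of the peak centre from the TSS in kb (x axis), for the 4688 TSS-near peaks; the bins next to the TSS hold 1692 and 1369 peaks. Right, percent of peaks within 5 kb of a TSS (y axis; points with 95% Wilson intervals) in 10 nearly equal parts of the list ranked by p-value (x axis, best first), which goes from 65.5% to 42.3%.

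TSS-near peaks had a higher fold enrichment than the rest, by a small margin. Their median fold enrichment was 14.8 (n = 4688) against 13.8 for the other peaks (n = 4745), a difference of 1.02 with a 95% bootstrap interval of 0.82 to 1.3 (two-sided permutation test, p = 1e-05, the smallest the resamples can give). The difference in fold was 1.75 at an FDR of at most 1%. In tags per peak the medians were 11.5 and 10, a difference of 1.5 (two-sided permutation test, p = 1e-05). Its bootstrap interval of 0 to 2 reached equality. Fold depends on the background estimate as well as on the ChIP signal. Of the 5 peaks with the highest fold, 4 lay near a TSS. The highest fold, 50.65, was shared by a peak at −677 bp from the TSS of PPP6R1, a regulatory subunit of protein phosphatase 6 (chromosome 19, 55770407 to 55771022, hg19, 64 tags), and by a peak at −238 bp from the TSS of GTF2H2C, which encodes a TFIIH subunit (chromosome 5, 68855722 to 68855903, 21 tags). GTF2H2C has near-identical copies in the genome, so the placement of its reads is uncertain. SSBP1, a mitochondrial single-stranded DNA-binding protein, followed with 44.7-fold enrichment at −181 bp (chromosome 7, 141437776 to 141438213, 49 tags), and PHIP with 41.7-fold enrichment at −8 bp (chromosome 6, 79787897 to 79788141, 22 tags). A peak with no named gene reached the same 41.7-fold enrichment (chromosome 19, 2462844 to 2463456, 67 tags). The other TSS-near peaks in the first 10 belonged to NCBP3, an mRNA cap-binding factor (38.4-fold), C11orf2 (37.6-fold), GTF3C5, a subunit of the RNA polymerase III factor TFIIIC (37.1-fold), MTF2, a Polycomb partner, and KDM6B, a histone H3 demethylase (36.2-fold each), and USP30, a mitochondrial deubiquitinase (35.8-fold). These peaks lay between −180 and 164 bp from the TSS except that of KDM6B, at −2882 bp. The folds of the 5 highest peaks and of USP30 were whole multiples (12 to 17) of 2.98 within 0.01, so that peaks with different tag counts share a fold.

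Proteasome genes were next compared with all other protein-coding genes. Peaks lay near the TSS of 21 of 54 proteasome genes (38.9%, Wilson interval 27.0 to 52.2) against 3640 of 19920 other genes (18.3%), an odds ratio of 2.85 (95% interval 1.56 to 5.07; Fisher's exact test, adjusted p = 0.00193). By subunit class, peaks were found at 9 of 14 PSMD genes, most of which encode non-ATPase subunits of the 19S regulatory particle, and at 3 of 6 PSMC genes, its ATPases. The 9 PSMD genes include PSMD5 and PSMD9, which encode assembly chaperones of that particle. They were found at 4 of 11 PSMB and 2 of 8 PSMA genes, which encode the 20S core, at 1 of 4 PSME activator genes and at 0 of 4 PSMG genes, whose products assemble the 20S core; these classes were not tested against each other. The highest fold belonged to PSMF1, a proteasome inhibitor subunit (23.6-fold, 31 tags, chromosome 20, 1098969 to 1099368). ADRM1, a ubiquitin receptor (23.03-fold, 30 tags, chromosome 20, 60877665 to 60878037), and PSMD3 (22.3-fold, 64 tags, chromosome 17, 38136677 to 38137492) followed. PSMA1 reached 20.8-fold (33 tags, chromosome 11, 14541772 to 14542251) and PSMB7 19.6-fold (29 tags, chromosome 9, 127177687 to 127178058). PSMC3 (18.9-fold), PSMD11 (17.97-fold) and PSMD6 (16.9-fold) had 22 to 33 tags each, whereas PSMC2 (16.5-fold) and PSMD1 (16.3-fold) had 10 tags each. In 20 of the 21 genes the strongest peak lay within 0.5 kb of the TSS; the exception was PSME2, whose peak lay 4790 bp downstream. In 12 of the 21 its FDR was at most 1%. Among the 33 genes without a listed peak were PSMA2, PSMB5, PSMC5 and PSMD4; a weak or shared-promoter peak there would not be detectable in this list. Without peaks in dense clusters, 12 of the 54 genes had a peak and the comparison no longer passed the test (odds ratio 2.24, Fisher's exact test, adjusted p = 0.0669).

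**Figure D2:**
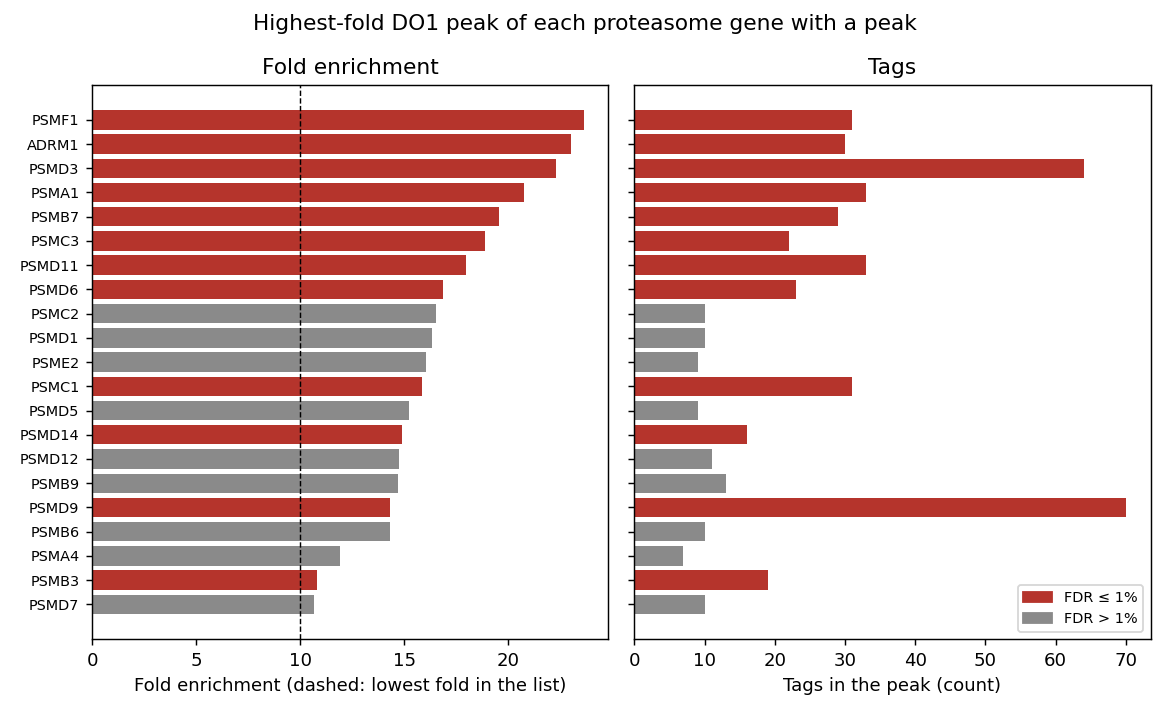
Fold enrichment (left x axis) and tag count (right x axis) of the highest-fold DO1 peak of each of the 21 proteasome genes with a peak within 5 kb of the TSS (y axis, ranked by fold; red, FDR at most 1%; grey, FDR above 1%). PSMF1 has the highest fold at 23.6, and peaks with few tags are mostly above 1% FDR.

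Several other gene groups of general cell maintenance also carried peaks more often than other genes, at 37.1% to 63.2% of their members. Peaks lay at 48 of 76 cytosolic ribosomal protein genes (63.2%, odds ratio 7.73, interval 4.74 to 12.8, Fisher's exact test, adjusted p = 6.6e-17), with 35.5-fold enrichment at RPL37, 29.8-fold at RPL10, 28.5-fold at RPS20 and 26.4-fold at RPS7. Of 35 core spliceosome genes 18 had a peak (51.4%, odds ratio 4.74, adjusted p = 6.1e-05 by Fisher's exact test), among them U2AF2 (26.4-fold), SNRPD3 (23.8-fold), SF3A3 (22.4-fold) and SNRPD1 (21.6-fold). Of 28 chromatin methyltransferase and acetyltransferase genes 13 had a peak (46.4%, odds ratio 3.87, adjusted p = 0.00193 by Fisher's exact test), led by KMT2A (26.8-fold), SETD1A (20.9-fold), SETD1B (18.4-fold) and KAT6A (17.9-fold). Nucleotide synthesis genes had peaks at 12 of 30 members (40.0%, odds ratio 2.98, adjusted p = 0.018 by Fisher's exact test). They included the ribonucleotide reductase subunit genes RRM2 (20.9-fold, at −2004 bp) and RRM1 (17.8-fold), thymidine kinase TK1 (19.02-fold) and CTPS1 (18.1-fold). Heat shock and chaperonin genes had peaks at 11 of 28 members (39.3%, odds ratio 2.89, adjusted p = 0.0235 by Fisher's exact test), including HSPA9 (18.7-fold), CCT7 (17.4-fold), HSP90AB1 (17.3-fold) and CCT4 (15.8-fold). Ubiquitin and p97 pathway genes had peaks at 13 of 35 members (37.1%, odds ratio 2.64, adjusted p = 0.018 by Fisher's exact test), among them the polyubiquitin gene UBB (25.6-fold) and UBQLN1 (18.6-fold). Complex I genes had peaks at 10 of 37 members (27.0%, odds ratio 1.65, interval 0.713 to 3.53), which did not pass the test (adjusted p = 0.25 by Fisher's exact test), although NDUFS3 (33.1-fold), NDUFS7 (26.8-fold) and NDUFB3 (23.8-fold) had strong peaks; NDUFA10 followed with 17.9-fold. Ribosomal protein genes and HSP90AB1 have many processed pseudogenes, and HSPA1A and HSPA1B are near-identical, so read placement at such genes is less certain. Fewer genes had a peak under stricter settings, and several calls were lost there with odds ratios that stayed above 1: at an FDR of at most 1% the odds ratio was 2.05 for chromatin enzymes, 2.55 for the ubiquitin list, 3.36 for the heat shock list (Fisher's exact test, adjusted p = 0.051) and 1.89 for nucleotide synthesis, and without dense clusters it was 2.14, 1.96 and 1.7 for the chromatin enzyme, ubiquitin and heat shock lists. Calls were also lost among the 4795 peaks with the highest fold for chromatin enzymes (2.66) and the heat shock list (1.73), among the 4734 with the best p-value for the ubiquitin list (2.32) and within 1 kb of the TSS for nucleotide synthesis (2.33). The ribosomal protein and spliceosome calls held in all of these settings, with odds ratios of 3.21 and 4.1 without dense clusters and 10.2 and 9.3 at an FDR of at most 1%.

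Lists tied to p53 and to known partners of mutant p53 did not pass the test. Among canonical targets of wild-type p53, 12 of 38 had a peak (31.6%, odds ratio 2.06, interval 0.946 to 4.23, Fisher's exact test, adjusted p = 0.104). They included DDB2 (21.3-fold), PLK3 (20.9-fold), FBXO22 (17.9-fold) and the cell cycle inhibitor CDKN1A, with 3 peaks, the strongest at 16.4-fold and 3920 bp downstream of the TSS; MDM2, BAX, BBC3 and FAS had none. NRF2 antioxidant targets had peaks at 9 of 29 protein-coding members (31.0%, odds ratio 2.01, interval 0.804 to 4.62, Fisher's exact test, adjusted p = 0.132). Those with the highest fold were TALDO1 (20.9-fold, 7 tags, FDR 6.38%), TXN (18.6-fold, 29 tags), SQSTM1 (18.1-fold) and UGDH (17.3-fold). No peak was listed at NQO1, GCLM and TXNRD1. In the list of the p53 family, the NRF2 axis and partner factors, 7 of 21 members had a peak (33.3%, odds ratio 2.23, interval 0.761 to 5.91, Fisher's exact test, adjusted p = 0.132). These included KEAP1, the NRF2 inhibitor (18.9-fold, 33 tags), MYC (18.6-fold, 32 tags), NFE2L2, which encodes NRF2 (17.9-fold, 9 tags, FDR 8.82%), and MAFK (14.9-fold). Mevalonate and sterol genes had peaks at 7 of 25 members (28.0%, odds ratio 1.73, interval 0.612 to 4.36, Fisher's exact test, adjusted p = 0.25), among them TM7SF2 (17.9-fold) and SREBF1 (13.2-fold). Cell cycle genes with NF-Y promoters had peaks at 2 of 22 members, BIRC5 (11.9-fold, 7 tags, FDR 18.7%) and E2F1 (10.7-fold, 8 tags, FDR 20.2%), an odds ratio of 0.445 (interval 0.0504 to 1.83, Fisher's exact test, adjusted p = 0.43). The intervals of these lists are wide and include odds ratios close to that of the proteasome list except for the cell cycle list. No list here passed the test in another setting. Without dense clusters the odds ratio of the p53 family list was 0.823. At an FDR of at most 1% that of the NRF2 list was 3.21 (Fisher's exact test, adjusted p = 0.0517) and that of the mevalonate list 1.07 (1.09 among the 4795 peaks with the highest fold). No member of the cell cycle list had a peak at an FDR of at most 1%, among the 4795 peaks with the highest fold or among the 4734 with the best p-value.

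Genes typical of the basal and mesenchymal state, to which MDA-MB-231 belongs, carried peaks more often than other genes, while the luminal, immune and neuronal lists did not pass the test. Peaks lay at 14 of 30 basal and mesenchymal genes (46.7%, odds ratio 3.91, interval 1.77 to 8.56, Fisher's exact test, adjusted p = 0.00168), including THBS1 (20.9-fold), CAV1 (19.02-fold), the intermediate filament gene VIM (18.2-fold) and CCN1 (17.5-fold, 5 peaks). Luminal epithelial genes had peaks at 4 of 22 members (18.2%, odds ratio 0.99, interval 0.244 to 3.01, Fisher's exact test, adjusted p = 1), CLDN4 (20.9-fold), SPDEF (15.2-fold), ERBB2 and ERBB3 (14.9-fold each); ESR1, GATA3 and FOXA1 had none. Matrix and adhesion genes had peaks at 8 of 30 members (26.7%, odds ratio 1.62, interval 0.624 to 3.79, Fisher's exact test, adjusted p = 0.266), including PCDH7 (22.4-fold), LAMA5 (18.03-fold), COL1A1 and COL12A1 (17.9-fold each). Long neuronal genes had peaks at 2 of 27 members, WWOX (14.3-fold) and FHIT (12.5-fold), and immune and blood genes at 1 of 25, CD79A (17.9-fold); neither list passed Fisher's exact test (adjusted p = 0.25 and 0.121). Olfactory receptor genes, which act in smell, had a peak at 1 of 392 members (0.255%, interval 0.045 to 1.43), at OR4A15 (13.8-fold), an odds ratio of 0.0111 (interval 0.000281 to 0.0624, Fisher's exact test, adjusted p = 4.14e-32). Several of these peaks held few tags. That of LAMA5 had 9 (FDR 11.23%). Those of ERBB2, ERBB3, COL12A1, WWOX, FHIT, CD79A and OR4A15 had 8 each, at FDRs of 4.76% to 13.79%. In all, 8 of the 19 lists had peaks more often than other genes and 1 less often. The basal and mesenchymal call did not hold without dense clusters (odds ratio 2.38, Fisher's exact test, adjusted p = 0.234) or among the 4795 peaks with the highest fold (odds ratio 2.43, Fisher's exact test, adjusted p = 0.137). The odds ratio of the luminal list was 1.77 in the latter peaks and 0.372 without dense clusters, where 1 member had a peak. That of the matrix list was 0.878 at an FDR of at most 1%. Over all settings the odds ratios, each from at most 2 members with a peak, went from 0 to 0.625 for the neuronal list, from 0 to 0.331 for the immune list and from 0 to 0.0196 for the olfactory receptor list.

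**Figure D3:**
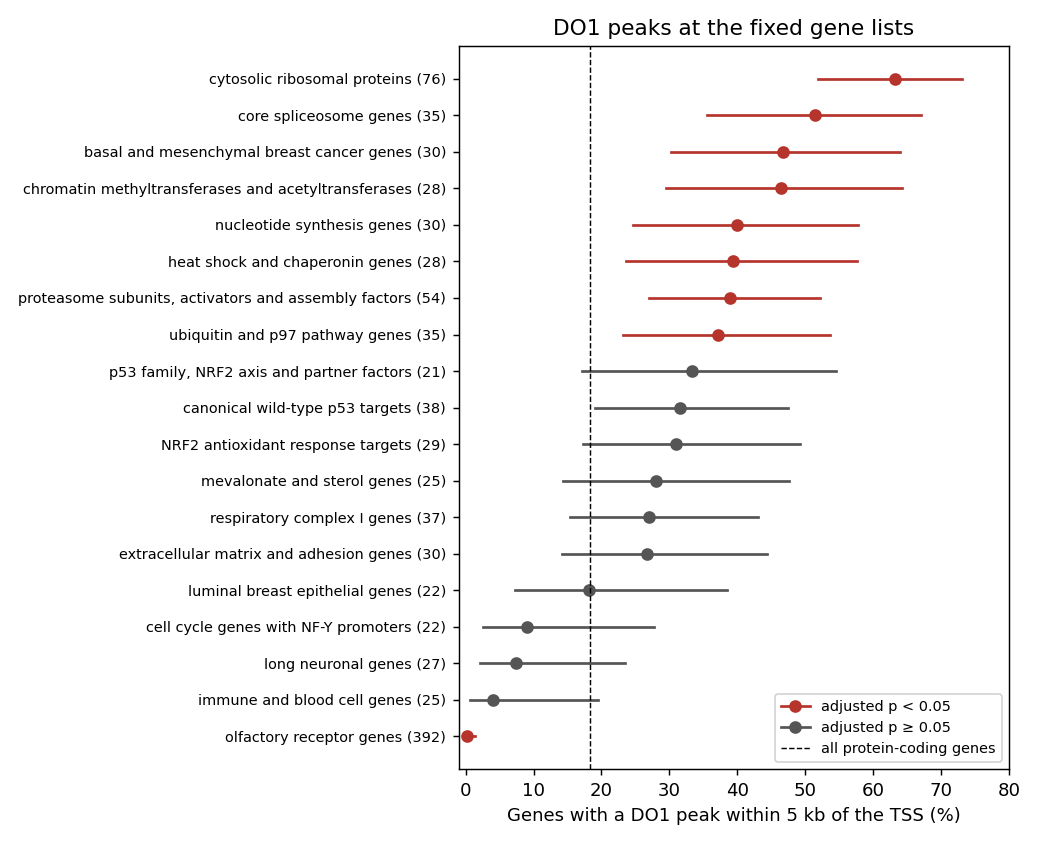
Percent of genes with a DO1 peak within 5 kb of the TSS (x axis; points with 95% Wilson intervals) in each of the 19 gene lists (y axis, number of members in parentheses); red lists passed Fisher's exact test after adjustment and the dashed line marks the 18.3% of all protein-coding genes. Cytosolic ribosomal proteins are highest at 63.2% and olfactory receptor genes lowest at 0.255%.

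Peaks were unevenly spread over the chromosomes relative to their protein-coding genes. Of 23 chromosomes, 7 held more and 7 held fewer peaks than expected (exact binomial tests, Benjamini-Hochberg adjusted). These tests treat peaks as independent, but 3571 peaks lay in dense clusters, so the p-values are likely too small. Chromosomes 5 (588 peaks, 1.38 times the expected number, exact binomial test, adjusted p = 2.85e-13), 10 and 17 (1.36 times each) and 20 (1.31 times) were highest. Chromosome X was lowest, with 86 peaks or 0.215 times the expected number (exact binomial test, adjusted p = 1.04e-81), followed by chromosome 21 (0.399 times) and 22 (0.681 times). MDA-MB-231 is aneuploid, and neither DNA copy number nor chromosome length entered these expectations. Leaving out dense clusters removes peaks where they are dense, so it lowers chromosomes with many such clusters by construction; chromosome 17 then stood at 0.598 times the expected number. Among the 4795 peaks with the highest fold chromosome 5 stood at 1.12 times and chromosome 20 at 0.846 times (exact binomial tests, adjusted p = 0.208 for each). The deficit of chromosome 22 did not pass the test in the latter peaks (0.988 times) or without dense clusters (0.884 times). It was larger at an FDR of at most 1% (0.296 times). Chromosome 21 stood at 0.642 times without dense clusters.

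**Figure D4:**
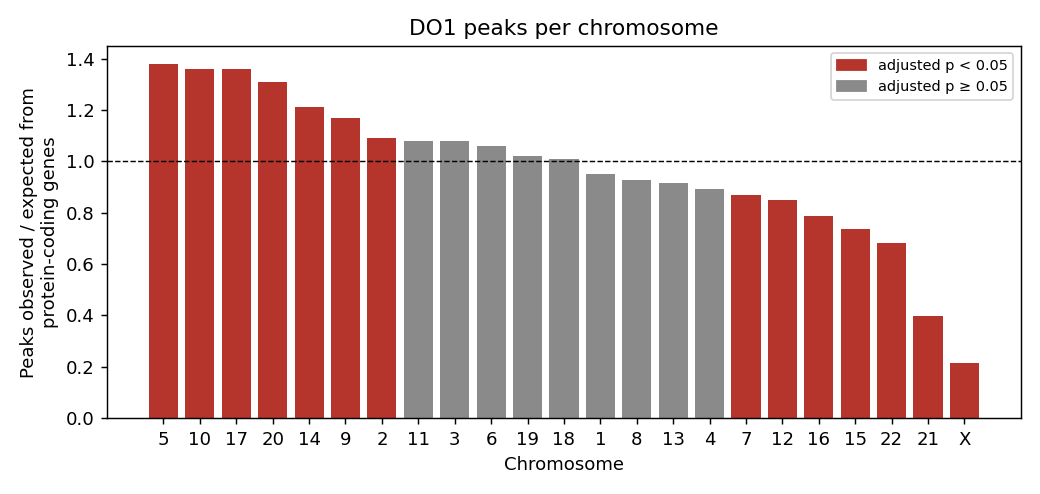
Observed number of DO1 peaks divided by the number expected from each chromosome's share of protein-coding genes (y axis, from 0; dashed line at equality) for the 23 chromosomes (x axis, ranked); red bars passed the exact binomial test after adjustment. Chromosome 5 is highest at 1.38 and chromosome X lowest at 0.215.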

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

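With 1 library per group, leaving out a replicate was not possible, and no paired analysis was possible because no group has more than 1 library. The alternatives at an FDR of at most 1%, except for the number of peaks, the splitting of readthrough gene names and the pool without ribosomal proteins were added after seeing the data. The number of peaks was 5026 at an FDR of at most 5%, 2845 at 1% and 8127 after merging within 1 kb. The share of peaks near a TSS was 54.9% in the 4734 peaks with the best p-value, 55.1% in the 4795 with the highest fold, 57.5% at an FDR of at most 1%, 46.3% without dense clusters (3571 peaks removed) and 39.2% with a 1 kb window, which is narrower by construction. The higher fold of TSS-near peaks kept its direction and side of the threshold in the 4 alternatives that do not select peaks by fold itself, with differences from 0.86 to 1.75. The p-value and the FDR rest on the same comparison of ChIP with background as the fold, so the peaks selected by them say little about stability. The difference was 1.18 without dense clusters and 0.92 within 1 kb of the TSS. The 4795 peaks with the highest fold were selected by the value compared, so their difference of 0.585 says nothing about stability. Proteasome genes kept theirs in 6 of 7 alternatives (odds ratios 2.78 to 4.0); without dense clusters the odds ratio was 2.24 (Fisher's exact test, adjusted p = 0.0669), with 12 genes in place of 21. The number of lists with more peaks than other genes was 5 in the peaks with the highest fold, 3 without dense clusters and 4 at an FDR of at most 1%, against 8 in the full list; fewer genes had a peak under each of these filters. The olfactory receptor list stayed below other genes in each alternative that could hold it. The number of chromosomes past the test was 6 in the peaks with the highest fold and 17 in each of the other 3 settings, against 14. Without dense clusters the ratio of observed to expected peaks crossed 1 and passed the test for chromosomes 17 (0.598), 11 (0.76), 19 (0.348), 13 (1.47), 4 (1.39) and 7 (1.18), and crossed it without passing for 15 (1.06) and 6 (0.981). That filter removes peaks where they are dense, so it shifts the ratios from chromosomes with dense peaks to the others by construction. Chromosome 6, at 1.06 in the full list without passing, was lower in the peaks with the highest fold (0.754, exact binomial test, adjusted p = 0.000177) and higher in those with the best p-value (1.22, adjusted p = 0.000973) and at an FDR of at most 1% (1.35, adjusted p = 4.48e-05). The other crossings did not pass the test. They were in the peaks with the highest fold for chromosomes 20 (0.846), 14 (0.936), 11 (0.986), 3 (0.993), 18 (0.957), 8 (1.01) and 13 (1.08), in those with the best p-value for chromosomes 2 (0.956) and 18 (0.938) and, by less than rounding shows, 1 (1.0), and at an FDR of at most 1% for chromosomes 2 (0.941) and 18 (0.884). Odds ratios crossed 1, without passing the test, for the luminal list in the peaks with the highest fold (1.77) and at an FDR of at most 1% (1.23), for the p53 family list without dense clusters (0.823) and for the matrix list at an FDR of at most 1% (0.878); without dense clusters that of the luminal list was 0.372. The cause was not tested for any of these odds ratios, nor for the chromosomes in the settings other than the removal of dense clusters. TSS windows wider than 5 kb, own assignment of genes, matching on gene length, random placement of peaks, expectations by chromosome length and all motif tests were not run, because the list names genes within 5 kb only and no genome or annotation of its build was used here. At its lower end the list holds peaks of 7 tags, and how far depth limits it was not tested.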

Other observations

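Some comparisons were chosen after the results they bear on had been seen, at least in part. They are the gene families, the proteasome test at an FDR of at most 1% and the share within 0.5 kb above the background floor. A hand-picked set of immediate early genes, which respond to growth factors within minutes, had a peak near the TSS at 19 of 26 members. The set includes genes whose peaks had already been seen, so this count is a description and not a test. They included ZFP36 (21.7-fold, 4 peaks), MYC (18.6-fold), CCN1 (17.5-fold, 5 peaks), FOSL1 (16.7-fold, 4 peaks), EGR1 (16.5-fold), IER2 (16.3-fold, 7 peaks), FOS (13.3-fold) and JUN (13.2-fold); several of these peaks lay away from the TSS, such as those of ZFP36 at −2767 bp, EGR1 at −1383 bp and JUN at −1275 bp. The genes with the most peaks within 5 kb were IER2 and HEXIM1, an inhibitor of the elongation factor P-TEFb, with 7 each.

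Other families were taken by their symbols and compared by Fisher's exact test, with adjustment over 10 sets that include the one above. General transcription factor, Mediator and RNA polymerase subunit genes had peaks at 38 of 101 members (37.6%, odds ratio 2.71, interval 1.76 to 4.12). Some of these genes were among the strongest peaks that prompted the comparison, so this count too is a description and not a test. They included GTF3C5 (37.1-fold), GTF3C3 and MED23 (35.8-fold each), POLR2A (32.8-fold), GTF2H4 (27.9-fold) and MED18 (27.7-fold). Translation initiation factors (25 of 55, odds ratio 3.73), mitochondrial ribosomal proteins (28 of 77, odds ratio 2.56), cytoplasmic aminoacyl-tRNA synthetases (7 of 18, odds ratio 2.84, Fisher's exact test, adjusted p = 0.0418, though with an interval of 0.932 to 8.03 that includes equality) and ZNF zinc finger genes (136 of 517, odds ratio 1.61) also had more peaks than other genes. Keratin and keratin-associated genes had fewer (7 of 152, odds ratio 0.214), as did taste, chemokine and serotonin receptors (0 of 61). Replication-dependent histone genes (14 of 70, odds ratio 1.11, interval 0.572 to 2.03) and solute carriers (69 of 386, odds ratio 0.969, interval 0.734 to 1.26) did not pass the test.

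The enrichment of the proteasome list was weighed against the signal at widely expressed genes in general. The share of proteasome genes with a peak was below that of the pooled members of the ribosomal protein, spliceosome, complex I and chaperone lists, by a difference that did not pass the test (21 of 54 against 87 of 176, or 49.4%; odds ratio 0.651, interval 0.331 to 1.26, Fisher's exact test, p = 0.213), and those pooled members stood above the remaining genes themselves (odds ratio 4.45, interval 3.27 to 6.07). The ribosomal proteins raise the pooled share; without them, a comparison chosen after seeing the data, it was 39 of 100, with an odds ratio of 0.995 (interval 0.475 to 2.07) for proteasome genes against the pool and 2.88 (interval 1.87 to 4.38) for the pool against the remaining genes. This is consistent with a signal at promoters of active genes in general, of which the proteasome would be a part; open chromatin, non-specific capture and wide binding of mutant p53 all predict it, and the IgG library, which bears on this, was not analysed here and no biological explanation was tested. Of the pooled lists, only complex I did not pass the test against other genes (10 of 37, odds ratio 1.65). No expression data entered these comparisons. False peaks near the threshold are argued against as the whole cause for the proteasome list, since with peaks of at most 1% FDR its odds ratio was 3.53 (interval 1.69 to 6.85). That comparison was chosen after the counts had been seen, and it does not bear on the proteasome peaks above 1% FDR.

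The gathering at the TSS was weighed against the way background was estimated. In 2342 peaks (24.8%) the fold was a whole multiple of 2.98 within 0.01, against 0.671% for multiples by chance, a step that would arise where the background estimate sat at a genome-wide floor and the input added nothing locally. TSS-near peaks made up 54.4% of these (interval 52.3 to 56.4) and 48.16% of the others (interval 47 to 49.3, Fisher's exact test, p = 2.02e-07). The floor may account for some of this difference, but these peaks were not matched with the others for strength. The TSS-near share was also higher in the peaks with the highest fold (55.1% against 49.7% in the full list). The part of the floor was therefore not separated here from that of peak strength. The gathering was also present above the floor: among TSS-near peaks with such a background, 66.41% lay within 0.5 kb of the TSS. An even spread would give 10%. The counts already seen forced this share to be high, so it cannot serve as a test of the floor as the whole cause. No biological explanation was tested, for want of another group with peaks.

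The list ends at a fold of 10. The first non-zero FDR step, which covers ranks 370 to 1281 of the list, would need ranks 1.05 times those in the list (median over 912 peaks) if it counted 1 swapped-control peak. The FDR is rounded to 0.01, and 63.9% of these peaks had a rank below what that rounding allows, while the others give no evidence of missing peaks. The list analysed here may therefore lack some of the called peaks with the best p-values (4.72% at the median ratio, before allowing for rounding). This is consistent with removal of peaks below a fold of 10, though another rule that removed peaks from these ranks or above, before or after deposit, could give the same ratio.

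A total of 13 peaks held more than 100 tags, and 8 of these had no named gene. The peak with the most tags (838, chromosome 18, 18517113 to 18519217) had a fold of 10.35, so its tags divided by its fold were 80.97 against a median of 0.781 over all peaks. The next were at chromosome 21, 9825439 to 9826376 (228 tags, 12.3-fold), near PMF1-BGLAP on chromosome 1 (192 tags, 14.2-fold) and at chromosome 2, 92296383 to 92296961 (188 tags, 10.4-fold). Another 4 lay on chromosome 10 between 42380025 and 42399591. In the 8 peaks with no named gene, tags divided by fold were 10.24 or more. Whether these peaks reflect binding or uncertain read placement was not tested. No peaks were removed by genomic region, so these peaks count in the totals and the chromosome ratios above.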
